A study of Mus musculus with 2 samples.

How the data were processed

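Long-read RNA sequencing (PacBio, per the name of the protocol in the labels) was applied to total RNA of the left cerebral cortex of C57BL/6 mice (strain B6NCrl in the labels) aged 6 months. The series holds 1 group with 2 biological replicates, each from its own tissue sample and each made from 2 µg of RNA with ERCC and SIRV spike-in RNAs added, per the labels. Both tissue samples carry the same donor entry in the labels, and nothing in the labels names the individual animals, so the spread between the replicates may be partly technical. A free-text label calls the animals male, whereas the sex field was left uncollected.

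The deposited values are read counts, that is, whole numbers of long reads assigned to each transcript model of 1 library, not normalized, per the file headers. The transcript models and their classes come from TALON, a tool that assigns each long read to an annotated or a newly built transcript model, per the source column of the deposited annotation. The reads were placed on mm10 with the GENCODE M21 annotation, per the descriptions deposited with the counts. The aligner, its version, any correction of the reads, any filter on reads and the handling of strand are not given in the sources used here. Each library was annotated on its own, so that model identifiers are not shared between them, and the replicates were not pooled. Models were therefore matched between the libraries by chromosome, strand and ordered introns (the intron chain).

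The classes are annotated chains (Known), incomplete matches to an annotated chain (ISM), chains that join annotated splice sites in a combination absent from the annotation (new in catalogue, NIC), chains with at least 1 unannotated splice site (not in catalogue, NNC), genomic models, antisense models and intergenic models. Reads of all models of an annotated gene were summed per gene. CPM was computed from the deposited counts as the usual depth-scaled count of a gene, with the reads of annotated genes in that library as the denominator. Such genes took 96.8% of the reads in replicate 1 and 97.3% in replicate 2, and the remainder belonged to spike-ins and to antisense and intergenic models.

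Replicate 1 held 2740617 reads in 236593 models and replicate 2 held 2538854 reads in 226996 models. One read of an annotated gene equalled 0.377 CPM in replicate 1 and 0.405 CPM in replicate 2, and a count of 0 allowed up to 3 reads, or 1.13 and 1.21 CPM. Shares of reads have 95% Wilson intervals. Reads come from PCR-amplified cDNA without molecular identifiers in the files used, so intervals and floors cover counting error only. Values are given as mean ± SD over the 2 libraries.

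With a single group there is no contrast between conditions. Instead, each gene with at least 20 reads in both libraries together was tested between the libraries with an exact two-sided binomial test on its reads, with the library totals as the null share and Benjamini-Hochberg adjustment at 0.05. That test compares these 2 libraries on counting error, not conditions. The spread beyond counting error was the square root of the common dispersion of edgeR 4.0.16 (estimateDisp, intercept only, TMM scaling, genes with at least 10 reads in both libraries together), the biological coefficient of variation (BCV). Log2 ratios were computed on CPM with 0.5 added. A fold against 0 reads is a bound against the floor of 3 reads in the library at 0.

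Lists of genes for cell types, layers, neighbouring brain regions and functions were fixed before the data were examined, as were the tests, the settings to be varied and the genes to be named. The rule named the 15 nuclear genes with the highest mean CPM, the top 3 members of each list and every member with 0 reads, the 5 genes with the largest fold in each direction among those called, the 20 main transcripts and 20 cassette exons with the most reads in a fixed set of alternatively spliced genes, the 8 microexons with the most reads, and the unannotated models with the most reads found in both libraries (5 of annotated genes, 3 intergenic, 3 antisense). Some genes that this rule names are not reported here, and they remain in the sums and counts. Each list was tested on its summed reads with the same binomial test, adjusted over 31 lists, and its median log2 ratio was ranked among 10000 random lists of the same size matched on mean expression. Counts adjusted over the list alone include all members with reads, without the minimum of 20. The ribosomal protein list was defined by name prefix and also takes in Rps6k kinases and pseudogenes.

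The main transcript share is the percentage of a gene's spliced reads in its most-read intron chain, for genes with at least 50 such reads, compared between libraries with Fisher's exact test. Percent inclusion of an internal exon is inclusion reads over inclusion and skipping reads, for exons with at least 20 such reads and at least 5 of each kind. Differences in inclusion between the libraries were tested with Fisher's exact test, a test added after the data were seen. Microexons (at most 27 nt) were compared with longer cassette exons by a permutation test of 100000 resamples, with an interval from 2000 bootstrap draws. Intron chains with at least 5 reads in 1 library were looked up in the other, and unannotated chains were compared with annotated ones by Fisher's exact test.

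The alternatives were TMM factors and DESeq2 1.42.0 size factors as scaling, no read minimum, the binomial variance inflated by the edgeR dispersion, other read minimums, subsets of transcript classes, another definition of skipping, other length classes and each replicate on its own. Removal of a lowess trend of the log2 ratio on transcript length (fraction 0.1), exon subsets by inclusion or annotation, and chains of 5 to 9 reads were added after the data were seen. So was the lookup of the genes with the largest folds in the other library, by the same intron chain under another gene or, for single-exon reads, by an overlap of at least 50% of the longer model. So were the sums of each list without the member whose reads lay furthest from the null share, adjusted over the lists, and the calls without genes that have a chain assigned to another gene in the other library. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

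The procedures were tested on simulated data. With 2-fold differences placed in genes at the real depths, 62.1% were called among 11787 genes, and 93.5% of 4-fold differences were called, with 5 unchanged genes called. With a length trend added and removed again, 60% and 92.8% were called among 11700 genes, with 11 unchanged genes called, against 2046 when the trend was left in. These simulated counts held counting error only, without the spread between the real libraries (BCV 0.258). The unchanged genes called therefore do not measure false calls in the real data. A BCV of 0.3 was recovered as 0.301 over 13395 genes. Percent inclusion was recovered with a mean error of 0.0784 and a largest error of 5.77 percentage points over 500 exons, 95% of shifts of 20 points in main transcript share were called among 1000 genes with 6 unchanged genes called, and the microexon test, over 5250 exons, recovered a difference of 20 points as 17.7 and gave p under 0.05 in 3% of 200 sets without a difference. The simulated reads for inclusion and main transcript share also held counting error only.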

Results

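The left cerebral cortex of adult mice was profiled with full-length transcript reads in 2 replicate libraries, so the data describe which genes and transcript structures this tissue expressed and how far the replicates differed. The libraries held 2740617 and 2538854 reads. Annotated genes with at least 1 read numbered 18949 in replicate 1 and 18543 in replicate 2, of which 16684 were detected in both and 12771 had at least 5 reads in both. Expression per gene correlated between the libraries across 20808 genes (Pearson r = 0.961 on log2 CPM, Spearman rho = 0.944), where genes are not independent replicates. The libraries differed beyond counting error, with a chi-square of 7.32 per degree of freedom, so they were treated as separate samples.

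The genes with the most reads were neuronal, glial and housekeeping genes. The ratio of the libraries followed transcript length (below), so reads may not have been recovered equally at all lengths. CPM therefore ranks genes by reads and may not rank them by abundance in the tissue. Hspa8 (mm10 9:40800984-40810087), which encodes a constitutive cytosolic chaperone, led with 15063 ± 2979 CPM (SD, n = 2 here and throughout). It was followed by Mbp (18:82475146-82585637), a main protein of compact myelin, at 7727 ± 912 CPM, and by Ckb, the brain creatine kinase, at 7409 ± 662 CPM. Tuba1a, an alpha-tubulin, stood at 6247 ± 1537 CPM and Snap25 (2:136713453-136782428), a SNARE protein of synaptic vesicle fusion, at 4427 ± 1022 CPM. Cpe, a prohormone-processing carboxypeptidase, reached 4317 ± 1329 CPM. The next genes were Ndrg4 at 3902 ± 577 CPM, the pyruvate kinase gene Pkm at 3872 ± 647 CPM and the translation initiation factor gene Eif4a2 at 3798 ± 209.8 CPM. Atp1b1, a sodium pump subunit, had 3649.8 ± 694 CPM, the elongation factor gene Eef1a1 had 3597 ± 1244 CPM and the lipid carrier gene Apoe had 3585 ± 534 CPM. Atp5a1, an ATP synthase subunit, had 3225 ± 189.6 CPM, gamma-actin Actg1 had 3203 ± 96.8 CPM and transferrin Trf had 2969 ± 527 CPM. These 15 genes took 7.70% ± 0.179 of the reads and the top 100 took 21.2% ± 0.345. Protein-coding genes took 98.6% ± 0.157 and long noncoding RNA genes 0.865% ± 0.0971. Hspa8, Tuba1a, Eef1a1 and Actg1 have near-identical relatives or pseudogenes, so their counts are uncertain to the extent that reads were shared.

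Most reads matched an annotated intron chain. Known chains took 74.6% ± 0.154 of the reads, and incomplete matches took 9.10% ± 0.0177, of which 66.4% ± 0.186 kept the 3′ end of the annotated chain without its 5′ end and 11.8% ± 0.642 kept neither end. Chains that recombined annotated splice sites took 7.12% ± 0.178 and chains with an unannotated splice site took 3.89% ± 0.0936. Genomic models took 3.13% ± 0.143, antisense models 1.85% ± 0.0491 and intergenic models 0.284% ± 0.00561. Single-exon reads made up 96.6% of antisense reads in replicate 1 and 97.0% in replicate 2. Models seen in a single read made up 61.3% and 61.9% of all models.

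**Figure D1:**
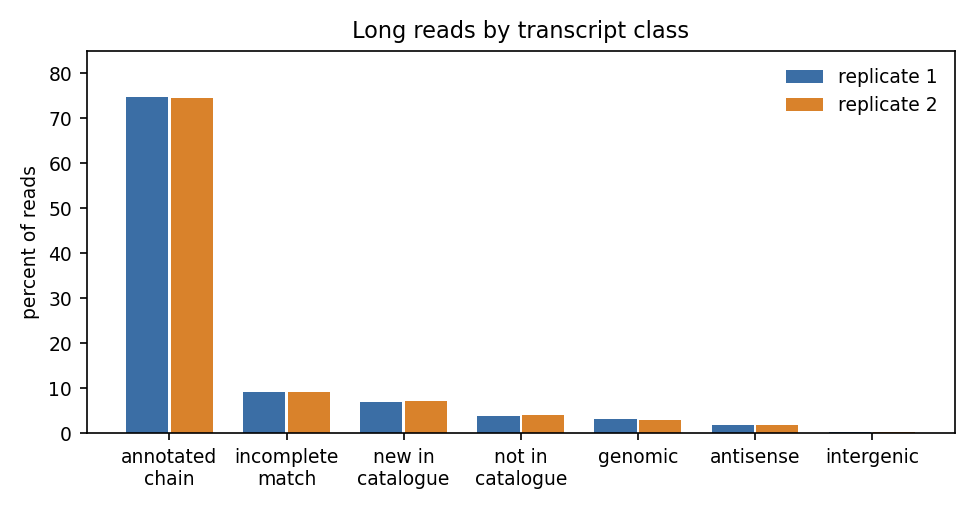
Percent of long reads (vertical axis) in each transcript class (horizontal axis), with 1 bar per replicate library. Annotated chains took 74.7% of reads in replicate 1 and 74.5% in replicate 2.

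Each glial and neuronal marker list had reads, with the largest sum among cell type lists for oligodendrocyte genes. The oligodendrocyte list summed to 13901 ± 1261 CPM and included Mbp and the myelin enzyme gene Cnp (1526 ± 109 CPM). Astrocyte genes summed to 5841 ± 8.12 CPM, led by the glycolytic enzyme gene Aldoc (2343 ± 537 CPM), the glutamate transporter gene Slc1a3 (947 ± 228 CPM) and the gap junction gene Gja1 (721 ± 226 CPM). Inhibitory neuron genes summed to 1508 ± 489.8 CPM, led by Gad1 (952 ± 465 CPM) and Gad2 (128 ± 40.2 CPM), the enzymes of GABA synthesis, and by Lamp5 (203 ± 39.8 CPM). Excitatory neuron genes summed to 346 ± 83.3 CPM, led by the kinase gene Camk2a (155 ± 83.3 CPM), Neurod6 (79.6 ± 12.3 CPM) and the vesicular glutamate transporter gene Slc17a7 (38.5 ± 0.545 CPM). The lists hold different genes, 11 for inhibitory and 7 for excitatory neurons, so their sums do not compare the amounts of cell types.

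Markers of other cell types were also read. Microglial genes summed to 974 ± 53.0 CPM, with the purinergic receptor gene P2ry12 at 99.7 ± 13.6 CPM and Tmem119 at 68.8 ± 17.3 CPM. Endothelial genes summed to 578 ± 41.0 CPM, with Itm2a at 232 ± 31.4 CPM, the tight junction gene Cldn5 at 168 ± 6.18 CPM and the transporter gene Slco1a4 at 84.3 ± 50.9 CPM. The choroid plexus and ependymal list summed to 548 ± 32.2 CPM, of which Enpp2 gave 463 ± 74.2 CPM, Ttr 81.9 ± 105 CPM and Ccdc153 3 reads in each library. Most of that sum came from Enpp2 alone, so it does not measure the amount of choroid plexus or ependymal cells. The mural cell list, led by Rgs5 (112 ± 8.43 CPM), Vtn (44.3 ± 4.995 CPM) and Kcnj8 (14.4 ± 2.03 CPM), summed to 184 ± 15.9 CPM. Blood genes summed to 46.5 ± 0.690 CPM, with the beta-globin gene Hbb-bs at 16.5 ± 4.97 CPM and the alpha-globin genes Hba-a1 and Hba-a2 at 11.6 ± 2.52 and 8.83 ± 1.83 CPM. Oligodendrocyte precursor genes summed to 41.6 ± 16.2 CPM, with Pdgfra at 19.8 ± 10.4 CPM, Gpr17 at 10.9 ± 0.553 CPM and Lhfpl3 at 5.53 ± 2.49 CPM, and meningeal genes to 37.3 ± 9.62 CPM, with the transporter gene Slc6a13 at 21.4 ± 6.33 CPM, Dcn at 10.7 ± 0.840 CPM and Lum with 2 and 7 reads. C1ql1 of the precursor list and Igf2 of the meningeal list had 0 reads in both libraries, which allows up to 1.13 CPM in replicate 1 and 1.21 CPM in replicate 2. The globin paralogs and other close copies may share reads.

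Layer and region markers covered a wide range. Deep-layer genes summed to 298 ± 0.406 CPM, led by the transcription factor genes Bcl11b (75.4 ± 7.39 CPM) and Etv1 (61.2 ± 10.3 CPM) and by Rprm (37.8 ± 19.6 CPM). Upper-layer genes summed to 99.9 ± 4.21 CPM, led by Cux1 (68.9 ± 5.13 CPM), Rorb (13.1 ± 0.385 CPM) and Otof (9.53 ± 1.45 CPM). The deep-layer symbol Ctgf has no entry in the annotation. Genes of the striatum list summed to 1816 ± 79.0 CPM, led by Ppp1r1b (628 ± 142 CPM), a phosphatase inhibitor of dopamine signalling, and also included Penk. The hippocampus list summed to 168 ± 12.4 CPM, of which Wfs1 gave 155 ± 14.2 CPM, C1ql2 8.11 ± 3.46 CPM and Prox1 5.11 ± 1.36 CPM. The thalamus list summed to 25.6 ± 8.47 CPM, led by Prkcd (20.3 ± 6.82 CPM), Lef1 (3.75 ± 1.57 CPM) and Tcf7l2 (1.56 ± 0.0789 CPM). The olfactory bulb list had 187 reads in replicate 1 and 441 in replicate 2, the cerebellum list 5 and 46 (Cbln1 5 and 6, Pcp2 0 and 3), and the hypothalamus list 61 and 2 (Avp 10 and 2, Hcrt 8 and 0). Y-linked genes were read in both libraries (Eif2s3y 241 and 188 reads, Ddx3y 156 and 205, Uty 43 and 57, Kdm5d 17 and 27), while Xist, the RNA of the inactive X chromosome, had 0 reads in both.

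**Figure D2:**
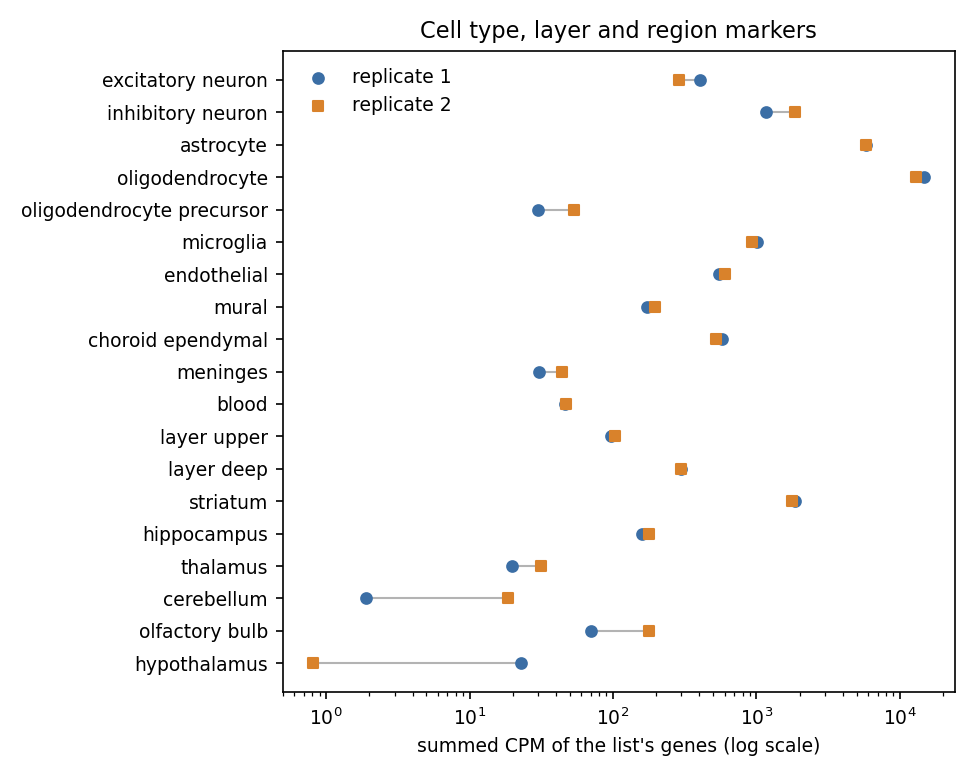
Summed CPM (horizontal axis, log scale) of each fixed list of cell type, layer and region markers (vertical axis), with 1 point per replicate library and a line joining the pair. The oligodendrocyte list is highest at 14793 and 13009 CPM, and the hypothalamus list has 23.0 CPM in replicate 1 and 0.810 in replicate 2.

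Among functional lists, nuclear oxidative phosphorylation genes summed to 15656 ± 824 CPM and were led, after Atp5a1, by Atp5b (2418 ± 215 CPM) and Sdha (1022 ± 236 CPM). Ribosomal protein genes summed to 11219 ± 2269 CPM, led by Rpl3 (2561 ± 1087 CPM), Rpl4 (926 ± 411 CPM) and Rplp0 (364 ± 200.05 CPM), neurodegeneration genes to 10545 ± 1078 CPM and presynaptic genes to 10320 ± 538 CPM. After Apoe, the neurodegeneration list was led by the prion protein gene Prnp (1766 ± 181 CPM) and by Apbb1 (1673 ± 51.04 CPM), whose protein binds the cytoplasmic tail of the amyloid precursor protein. After Snap25, presynaptic genes were led by the vesicle protein gene Syp (1564 ± 259 CPM) and the complexin gene Cplx1 (1022 ± 18.0 CPM). Postsynaptic genes summed to 3362 ± 699 CPM, led by the glutamate receptor gene Gria2 (735 ± 190.1 CPM) and Camk2b (660.2 ± 203 CPM). Splicing regulators summed to 1963 ± 149 CPM, led by Celf4 (596 ± 92.8 CPM), Mbnl2 (337 ± 34.4 CPM) and Ptbp2 (249 ± 29.7 CPM). Neuropeptide genes summed to 1535 ± 195 CPM, led by the granin genes Scg2 (624 ± 184 CPM) and Chgb (351 ± 110.5 CPM) and by the enkephalin precursor gene Penk (279.8 ± 102 CPM). Mitochondrial genome transcripts summed to 1500.5 ± 229.7 CPM, led by mt-Co1 (847 ± 193 CPM), mt-Rnr2 (313 ± 74.8 CPM) and mt-Cytb (71.8 ± 14.7 CPM). The long noncoding RNA list summed to 1049 ± 407 CPM, led by the imprinted Meg3 (671 ± 301 CPM), Snhg11 (204 ± 79.5 CPM) and Malat1 (62.3 ± 23.4 CPM). Immediate early genes summed to 1019 ± 104 CPM, led by Junb (309 ± 51.5 CPM), Arc (167 ± 34.9 CPM) and Dusp1 (136 ± 13.6 CPM), and proliferation genes to 76.6 ± 22.4 CPM, of which the replication clamp gene Pcna gave 53.0 ± 29.6 CPM and Mcm2 15.8 ± 5.77 CPM, with Ccnb1 at 5 and 10 reads.

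The replicates differed in many genes. Of 11789 genes tested, 3914 (33.2%) differed between the libraries at adjusted p under 0.05 by the exact binomial test with Benjamini-Hochberg adjustment, 1905 of them higher in replicate 1 and 2009 higher in replicate 2. Rpl3, a protein of the large ribosomal subunit, had 8830 reads in replicate 1 and 4424 in replicate 2, while App, the amyloid precursor protein gene, had 3018 and 4902 and Gad1 had 1652 and 3163. The test counts reads of these 2 libraries only. The BCV between them was 0.258, and with the variance inflated by that dispersion 13 genes were called (8 higher in replicate 1 and 5 in replicate 2). With DESeq2 size factors 2233 genes were higher in replicate 1 and 1352 in replicate 2, where the factors shift all log2 ratios by 0.10 (0.06 with TMM). The DESeq2 size factor was 1 for both libraries, so that setting compared counts without scaling for depth. Of the 3914 genes, 137 had an intron chain assigned to another gene in the other library.

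The ratio of the libraries followed transcript length. For the 573 genes with a mean model length above 1250 nt and up to 1500 nt the median log2 ratio of replicate 2 to replicate 1 was -0.97, and 526 of them were higher in replicate 1. For the 397 genes above 1000 nt and up to 1250 nt it was -0.83. The 83 genes of at most 500 nt had a median of 0.27, and the 1320 genes above 4000 nt and up to 6000 nt had a median of 0.31, with 1011 higher in replicate 2. After removal of this trend, a step added after the data were seen, 2141 genes differed, of which 1654 were among the 3914.

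**Figure D3:**
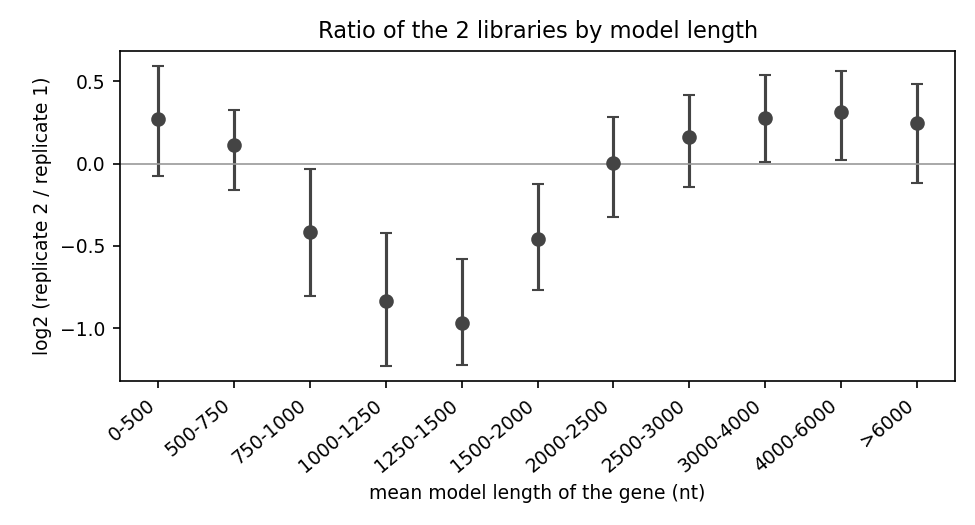
Log2 ratio of replicate 2 to replicate 1 (vertical axis) for genes grouped by mean model length in nt (horizontal axis), where points are medians over genes and bars span the quartiles. The median falls to -0.97 for genes above 1250 nt and up to 1500 nt and stands at 0.31 for genes above 4000 nt and up to 6000 nt.

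Most of the genes with the largest folds were ones whose transcripts were assigned to another gene in the other library, by a lookup added after the data were seen. The pseudogene Gm8290 had 46 and 0 reads, but 44 of the 46 carried an intron chain that was assigned to Zfp873 in replicate 2 (47 reads). Gm43674 had 42 and 0 reads, 39 of them on chains assigned to Gm43672 in replicate 2 (24 reads). Gm45021 had 0 and 76 reads, 72 of them on chains assigned to Repin1 in replicate 1 (81 reads). Gm20695 had 1 and 73 reads, 58 of them on chains assigned to Cluap1 in replicate 1 (88 reads), and Ncmap had 0 and 22, 14 of them on chains assigned to Rcan3 in replicate 1 (11 reads). Slc24a5 (31 and 0 reads) and Gm26786 (0 and 21 reads) had single-exon reads only, and in the other library all of them lay on the span of models assigned elsewhere. The counts of the genes with reassigned chains therefore give no fold in expression. For Slc24a5 and Gm26786 an overlap of spans does not show that the same transcripts were reassigned, so their folds are uncertain. Pmch, the melanin-concentrating hormone gene of hypothalamic neurons, had 42 and 0 reads, at least 13.0-fold higher in replicate 1. Gabra6, a GABA receptor subunit gene typical of cerebellar granule cells, had 0 and 37 reads, at least 13.2-fold higher in replicate 2. No intron chain of either was assigned to another gene in the other library. The bounds set the library at 0 to its floor of 3 reads.

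Of the 31 lists with reads, 24 differed between the libraries in summed reads, 14 higher in replicate 1 and 10 higher in replicate 2. Inhibitory neuron genes were 1.60-fold higher in replicate 2 (adjusted p = 2.9e-90 by the exact binomial test), with 3 members called higher in each library (6 of 11 adjusted over the list alone), but Gad1 carried the sum: without it the list had 1429 and 1416 reads (1.06-fold, adjusted p = 0.161). The median log2 ratio of the list was nevertheless 0.61 (percentile 99.9 among random lists), or 0.45 (99.86) with the length trend removed. Postsynaptic genes were 1.34-fold higher in replicate 2 (adjusted p = 2.19e-82), with 8 members called higher in replicate 2 and 1 in replicate 1 (9 adjusted over the list alone), and Gria2 and Camk2b were among the 8. Excitatory neuron genes were 1.41-fold higher in replicate 1 (adjusted p = 1.72e-12), with Camk2a higher in replicate 1 and Tbr1 in replicate 2 (2 adjusted over the list alone), and without Camk2a it had 507 and 472 reads (adjusted p = 1). Oligodendrocyte genes were 1.14-fold higher in replicate 1 (adjusted p = 8.77e-65), with 4 members higher in replicate 1 and 3 in replicate 2 (7 adjusted over the list alone). Long noncoding RNAs were 1.76-fold higher in replicate 1 (adjusted p = 8.27e-90), with Meg3, Snhg11, Malat1 and Neat1 called higher in replicate 1 and Snhg14 in replicate 2 (5 adjusted over the list alone). Ribosomal protein genes were 1.33-fold higher in replicate 1 (adjusted p = 3.99e-256), with 33 of 121 tested members higher in replicate 1 and 18 higher in replicate 2 (50 adjusted over the list alone), but after removal of the length trend the sum was 1.02-fold higher in replicate 2 (adjusted p = 0.00700), with 11 members higher in replicate 1 and 17 in replicate 2.

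Region lists also differed. Olfactory bulb genes were 2.53-fold higher in replicate 2 (adjusted p = 4.13e-28), with Doc2g (116 and 227 reads) and the dopamine synthesis gene Th (70 and 206 reads) both called (3 adjusted over the list alone, with Eomes). Hypothalamus genes were 28.4-fold higher in replicate 1 (adjusted p = 5.93e-15), and cerebellum genes 9.88-fold higher in replicate 2 (adjusted p = 6.78e-10), each with 1 member called (2 and 1 adjusted over the list alone). Without Pmch the hypothalamus list was 8.85-fold higher in replicate 1 (adjusted p = 0.000674), whereas without Gabra6 the cerebellum list had 5 and 9 reads (adjusted p = 0.373). In the choroid plexus and ependymal list the thyroid hormone carrier gene Ttr had 415 and 18 reads and was higher in replicate 1, while Enpp2 had 1089 and 1273 and was higher in replicate 2 (2 adjusted over the list alone). The list sum was 1.09-fold higher in replicate 1 (adjusted p = 0.0370 by the exact binomial test). Without Ttr it was 1.25-fold higher in replicate 2 (adjusted p = 1.68e-07 by the same test), where Enpp2 gave 1089 and 1273 of the 1100 and 1280 reads. The median log2 ratio of the whole list was 0.07, which is within the shift of 0.10 between scalings. The sums and medians also took opposite signs for the neurodegeneration list (1.16-fold higher in replicate 2, median -0.04) and the mitochondrial genome list (1.24-fold higher in replicate 1, median 0.15).

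More lists differed in their summed reads. Presynaptic genes were 1.08-fold higher in replicate 1 (adjusted p = 7.63e-17), with 4 members higher in replicate 1 and 5 in replicate 2 (9 adjusted over the list alone). Nuclear oxidative phosphorylation genes were 1.08-fold higher in replicate 1 (adjusted p = 2.38e-25), with 28 and 17 members called (48 adjusted over the list alone). After removal of the length trend they were 1.08-fold higher in replicate 2 (adjusted p = 8.05e-30), with 11 and 25 called. Splicing regulators were 1.11-fold higher in replicate 1 (adjusted p = 1.77e-07), with 6 and 3 called (11 adjusted over the list alone). Neuropeptide genes were 1.20-fold higher in replicate 2 (adjusted p = 4.72e-15), with 3 called each way (6 adjusted over the list alone), and in the neurodegeneration list 5 and 6 members were called (11 adjusted over the list alone, adjusted p of the sum 1.17e-62), against 1 and 5 without the length trend, where the sum was 1.43-fold higher in replicate 2 and the median 0.04. Apoe of that list (8507 and 9784 reads) moved from a log2 ratio of 0.30 to 1.21 with the trend removed. Microglial genes were 1.08-fold higher in replicate 1 (adjusted p = 0.0101), with 4 and 3 members called (9 adjusted over the list alone), but 1.13-fold higher in replicate 2 without the trend (adjusted p = 2.41e-05), with 0 and 2 called. Endothelial genes were 1.11-fold higher in replicate 2 (adjusted p = 0.00998), with 1 and 2 called (5 adjusted over the list alone). Oligodendrocyte precursor genes were 1.76-fold higher in replicate 2 (adjusted p = 0.000102, 1 member called by either count), and meningeal genes were 1.45-fold higher in replicate 2 (adjusted p = 0.0180, no member called and 1 adjusted over the list alone). Mitochondrial genome transcripts had an adjusted p of 9.05e-21, with 2 and 3 called (5 adjusted over the list alone), and turned to 1.30-fold higher in replicate 2 without the trend (adjusted p = 6.39e-29), with 0 and 8 called.

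Other lists kept their direction without the trend. Postsynaptic genes were then 1.12-fold higher in replicate 2 (2 members called higher in replicate 1 and 5 in replicate 2), inhibitory neuron genes 1.49-fold (1 and 3) and endothelial genes 1.43-fold (0 and 2). Splicing regulators were 1.21-fold higher in replicate 1 (7 and 0), oligodendrocyte genes 1.10-fold (4 and 1), presynaptic genes 1.05-fold (4 and 4) and long noncoding RNAs 1.88-fold (4 and 0). Single members carried other sums too, by a step added after the data were seen that left out the member that moved a sum most. This step was run only on sums with the length trend left in. Presynaptic genes without Snap25 were 1.12-fold higher in replicate 2 (adjusted p = 4.13e-23), astrocyte genes without Aldoc 1.24-fold (adjusted p = 1.87e-45) and proliferation genes without Pcna 1.56-fold (adjusted p = 0.0361). Neuropeptide genes without Scg2 (adjusted p = 0.640), endothelial genes without Slco1a4 (0.558), precursor genes without Pdgfra (0.101), meningeal genes without Slc6a13 (0.298) and thalamus genes without Prkcd (0.416) did not pass. With all members and the trend left in, median log2 ratios were 0.29 for neuropeptide (percentile 90.15 among random lists), 0.59 for endothelial (99.68) and 0.87 for precursor genes (99.11). They were 0.60 for meningeal (92.99) and 0.68 for thalamus genes (92.91).

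Differences of 4 further lists lost their call once the length trend was removed, and 1 list gained one. Striatum genes were 1.06-fold higher in replicate 1 (adjusted p = 0.00508, 3 and 2 members called, 5 adjusted over the list alone), against an adjusted p of 0.353 without the trend. Immediate early genes were 1.16-fold higher in replicate 1 (adjusted p = 3.78e-07, 3 and 1 called, 4 adjusted over the list alone), against 0.105. Proliferation genes were 1.52-fold higher in replicate 1 (adjusted p = 7.96e-05, with Pcna called by either count), against 0.353. Thalamus genes were 1.61-fold higher in replicate 2 (adjusted p = 0.0116, no member called by either count), against 0.0611. The sum of astrocyte genes did not pass (adjusted p = 0.927) although 4 members were called higher in replicate 1 and 7 in replicate 2 (11 adjusted over the list alone). Without the trend the sum was 1.09-fold higher in replicate 1 (adjusted p = 1.45e-13 by the exact binomial test), with 3 members called each way. Mural (adjusted p = 0.0782), blood (0.927), upper-layer (0.561) and hippocampus (0.153) genes did not pass and had no member called by either count, while deep-layer genes (0.980) had 2 and 1 members called (3 adjusted over the list alone) and Y-linked genes (0.0986) had 1, Ddx3y, called by either count.

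Most genes were read mainly as 1 intron chain. Among 8382 multi-exon genes the main chain held a median of 69.1% of the spliced reads (68.4% in replicate 1 and 70.0% in replicate 2), and in 5813 genes (69.4%) it held more than 50%. The main chain was annotated in 7172 genes (85.6%), an incomplete match in 628 and absent from the annotation in 582 (6.94%). Apoe-206 held 97.5% ± 0.373 of Apoe reads, Mobp-204 85.9% ± 0.708 of the reads of this myelin-associated gene, Pkm-202 85.9% ± 2.71, Snap25-201 85.7% ± 1.60, Rtn3-203 81.6% ± 0.823 and App-201 80.7% ± 5.02. Mbp-211 held 78.3% ± 4.07, Clu-201 73.6% ± 1.57, Cnp-201 68.3% ± 4.18, Ndrg4-202 68.0% ± 0.184 and Map4-206 66.6% ± 4.79. The main chain held less in Camk2b (Camk2b-209, 58.1% ± 1.13), Cdc42 (Cdc42-202, 55.9% ± 5.37), Ndrg2 (Ndrg2-202, 43.5% ± 2.79) and Gria2 (Gria2-201, 41.8% ± 2.75). In Tpm3 (65.8% ± 1.15), Apbb1 (59.1% ± 3.87) and Meg3 (28.6% ± 0.498) the main chain was absent from the annotation.

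The share of the main chain differed between the libraries in 203 of 8382 genes by Fisher's exact test with Benjamini-Hochberg adjustment, in 126 of them by at least 10 percentage points. Of the 203, 24 were among 321 genes with an intron chain assigned to another gene in the other library, and without those genes 172 differed. Mbp-211 was at 75.4% in replicate 1 and 81.1% in replicate 2 (adjusted p = 1.55e-39), App-201 at 77.1% and 84.2% (adjusted p = 3.85e-12) and Pkm-202 at 84.0% and 87.8% (adjusted p = 6.46e-12). Map4-206 was at 70.0% and 63.2% (adjusted p = 0.00339). Ndrg4-202 (adjusted p = 1) and Apoe-206 (0.327) did not pass. Incomplete matches, which would include truncated reads, enter the denominator, so the shares may depend on read completeness. Chains of a gene that differ in length may also shift in share with the length trend between the libraries. Neither shares nor exon inclusion were tested with that trend removed. Without incomplete matches the median share was 79.9% and 114 genes differed, and with known transcripts only 40 did.

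Cassette exons ranged from near skipping to near full inclusion. Over 10533 cassette exons in 4454 genes mean inclusion was 60.4% (60.2% in replicate 1 and 60.6% in replicate 2), 4047 exons were included in more than 90% of reads and 2004 in less than 10%. Inclusion correlated at r = 0.980 across 10191 exons, which are not independent replicates. Both ends matched an annotated exon in 8464 exons (80.4%). In the fixed set of genes 305 exons of 59 genes passed the read minimum, and 166 lay between 5% and 95% inclusion.

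Neighbouring exons of equal length gave complementary values. In Snap25 the 118 nt exon at 2:136770057-136770174 was included in 89.7% ± 2.31 of reads and its 118 nt neighbour at 2:136769743-136769860 in 10.2% ± 2.30. In Pkm the 167 nt exon at 9:59675029-59675195 was at 89.4% ± 0.131 and the 167 nt exon at 9:59675568-59675734 at 10.5% ± 0.143. Mbp included a 123 nt exon (18:82578936-82579058) in 14.2% ± 2.76 and a 78 nt exon (18:82561778-82561855) in 6.51% ± 1.59 of reads, and Ndrg4 a 39 nt exon (8:95712325-95712363) in 89.3% ± 2.32. All of these are annotated and coding along their whole length. The other 13 of the 20 exons with the most reads belonged to Mbp, Ndrg4 and Snap25 and were included in at least 99.4% or at most 0.0235% of reads on average.

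Exons between 5% and 95% inclusion were singled out after the data were seen. The 115 nt exons of Gria2, which encode alternative segments of an AMPA receptor subunit, were at 65.7% ± 0.386 (3:80691320-80691434) and 34.7% ± 0.473 (3:80690404-80690518). Ndrg2 included a 42 nt exon in 27.9% ± 1.58 and the calcineurin gene Ppp3ca a 30 nt exon in 90.8% ± 0.621 of reads. Camk2b had a 45 nt exon at 87.2% ± 0.313, Camk2g a 63 nt exon at 62.6% ± 0.720, and the myelin glycoprotein gene Mag a 45 nt exon at 73.8% ± 1.84. In Tpm3 the 76 nt exons at 3:90089048-90089123 and 3:90088401-90088476 were at 78.6% ± 2.45 and 21.6% ± 2.33. Inclusion differed between the libraries in 33 of 10533 exons by Fisher's exact test with Benjamini-Hochberg adjustment, 19 of them by at least 10 points, and 6 of the 33 lay in those 321 genes, without which 25 differed. The 33 included Mbp (123 nt, 16.1% and 12.2%, adjusted p = 4.79e-24), Snap25 and Ndrg4 exons and 5 exons of Bin1, an endocytic adaptor gene, where a 24 nt exon (18:32429700-32429723) was at 43.9% and 55.0% (adjusted p = 0.00307). Exons of the same gene share reads, as those of Bin1 and the complementary exons of Snap25 do, so the 33 are not independent events.

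**Figure D4:**
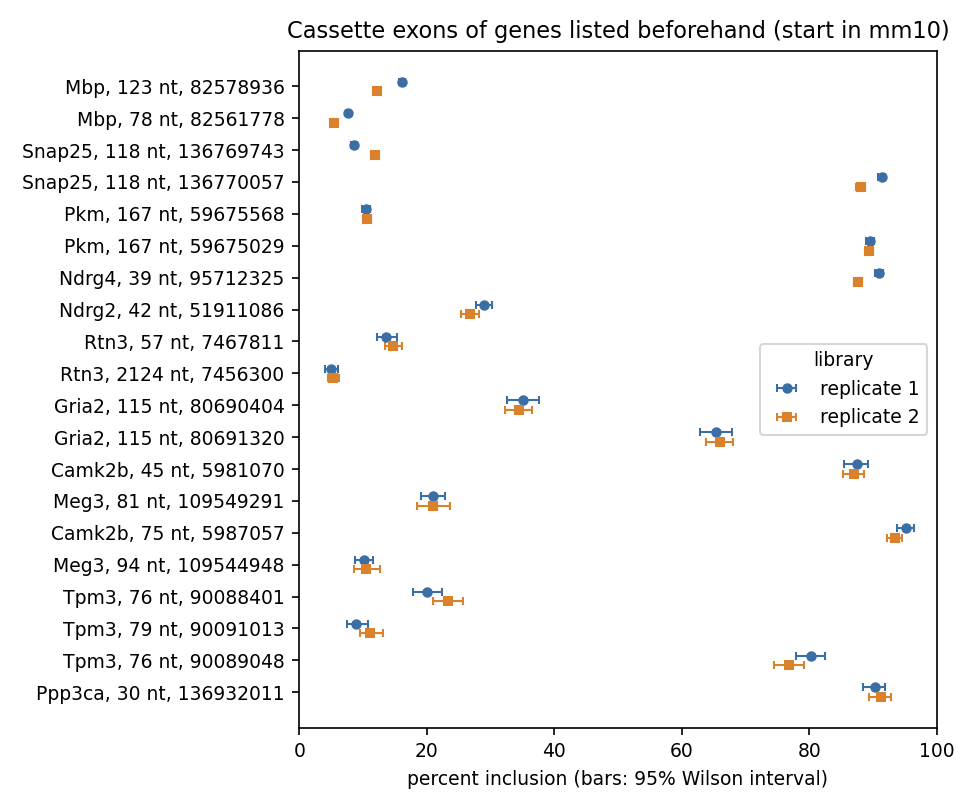
Percent inclusion (horizontal axis) of 20 much-read cassette exons between 5% and 95% inclusion in genes listed beforehand (vertical axis, with length and start in mm10), where points are replicate libraries and bars are 95% Wilson intervals. The intervals of both 115 nt exons of Gria2 overlap between the libraries, whereas the 123 nt exon of Mbp is at 16.1% and 12.2%.

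Microexons, a class of very short exons enriched in neurons, were compared with longer cassette exons. Their mean inclusion was 58.8% for 246 microexons and 60.4% for 10287 longer exons, a difference of -1.61 points (95% bootstrap interval -6.18 to 2.92, permutation p = 0.515), which did not pass. A length divisible by 3 was more frequent among microexons, at 67.1% against 41.9% (Fisher's exact test p = 4.04e-15). The most-read microexons were near complete inclusion or near complete skipping. Ppp1r1b included a 23 nt exon (11:98350885-98350907) in 99.7% ± 0.219, Nap1l4 a 23 nt exon in 98.6% ± 0.00811 and Bsg a 25 nt exon (10:79711256-79711280) in 91.6% ± 0.00990 of reads. Inclusion was 3.51% ± 0.954 for 24 nt of Pak1, 2.73% ± 0.0237 for 20 nt of Chmp1a, 0.552% ± 0.181 for 25 nt of Nap1l4, 0.475% ± 0.146 for 20 nt of Rapgef4 and 0.124% ± 0.0700 for 27 nt of Snap47. Whether the difference in mean inclusion passed, and its sign, depended on the exons entered. It passed at -8.56 points with known and new-in-catalogue transcripts only (permutation p = 0.00312) and at -5.91 points for exons of at most 51 nt (permutation p = 2.0e-05), and it turned to 3.6 points (permutation p = 0.133) among exons of 10% to 90% inclusion, a subset added after the data were seen.

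Intron chains absent from the annotation were mostly found again when they had at least 5 reads in a library. Of chains with at least 5 reads in replicate 1, 96.6% of those absent from the annotation and 99.1% of annotated ones were found in replicate 2 (Fisher's exact test p = 1.16e-41), and from replicate 2 to replicate 1 the values were 97.7% and 99.5% (p = 1.01e-33). With any number of reads, 32511 chains absent from the annotation were read in both libraries, which is 32.7% of the 99483 in replicate 1 and 33.1% of the 98231 in replicate 2. The most-read was a chain of Sept7, a septin cytoskeleton gene, with 2807 and 2831 reads or 82.1% of the gene's reads. As aligned, it lacks a 5 nt exon (9:25265302-25265306) of the annotated Sept7-201. The aligner and any correction of the reads are not known. Skipping of so short an exon therefore cannot be told apart from an alignment that did not place it. A chain of Apbb1 with 2445 and 2603 reads (59.0%) differs from Apbb1-201 by 1 further annotated intron (7:105574417-105581134). Chains of the antizyme genes Oaz1 (2288 and 1411 reads, 96.0%) and Oaz2 (1898 and 1576 reads, 92.0%), whose translation requires a ribosomal frameshift, read through a gap of 4 nt that the annotation enters as an intron (10:80828292-80828295 and 9:65686269-65686272). A chain of the dynactin gene Dctn2 (2139 and 1371 reads, 84.4%) starts an intron at 10:127267493 where Dctn2-201 starts it at 10:127267483. Chains of 5 to 9 reads, compared after the data were seen, gave 94.3% against 96.4% (Fisher's exact test p = 1.75e-05) and 95.9% against 97.9% (p = 1.72e-06).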

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

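The tests of the spike-in RNAs against transcript length were chosen after the length trend had been seen. Spike-in reads lie outside the comparisons of the report and stood far above the floor that a count of 0 allows (1.09 and 1.18 CPM of all reads in replicates 1 and 2). ERCC spike-ins had 4321 CPM in replicate 1 and 1388 in replicate 2, a ratio of 3.11. SIRV spike-ins had 6203 and 3431 CPM, a ratio of 1.81. Of 44 ERCC sequences with reads, 33 were read in both libraries, as were all 7 SIRV sequences.

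The ratio of the libraries followed transcript length among mouse genes, with a median log2 ratio of -0.97 for genes above 1250 nt and up to 1500 nt and of 0.31 for genes above 4000 nt and up to 6000 nt. ERCC RNAs with at least 20 reads and read in both libraries, which come from no animal, had a median log2 ratio of -1.82 at 1 to 1.5 kb (SD 0.259, n = 10) and of -0.55 under 0.75 kb (SD 0.252, n = 4). The difference of -1.27 (exact permutation p = 0.00999, two-sided) exceeds either SD and, among these better-read RNAs, argues against an expression difference between the animals as the whole source of the trend, since spike-ins would then show none. With an ERCC at 0 reads in 1 library let in it was -1.26 (largest SD 0.763), but with any number of reads (20 and 10 RNAs, 0.5 added to the CPM) it was -0.987, within the SD of 1.09 (permutation p = 0.110). A candidate explanation is that library construction or size selection recovered lengths differently in the 2 libraries, for which the same -1.27 is required, while the ERCC RNAs do not reach lengths above 4000 nt, so that part of the trend stays open.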

How the results depend on the processing

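Removal of the length trend, omission of genes with a chain assigned to another gene in the other library, and subsets of exons by inclusion or annotation and of chains by reads, were chosen after the data were seen; all other alternatives were fixed beforehand. The count of genes differing between the libraries (3914) fell to 13 with the variance inflated by the edgeR dispersion, as the added variance implies, and to 2141 with the length trend removed, and was 3717 with TMM factors, 3585 with DESeq2 size factors and 3545 with no read minimum. The BCV was 0.261 with DESeq2 size factors. With models of at least 2 reads, the share of annotated chains was 78.7% and that of both classes of unannotated chains 8.71%. The median main chain share was 97.7% with known transcripts only (40 genes with different shares), 79.9% without incomplete matches (114 genes), 73.0% at 100 reads, and 72.7% to 73.2% from either replicate alone. Mean exon inclusion was 65.6% with known and new-in-catalogue transcripts only, 56.8% with an exact skipping junction, 55.2% among 6058 exons of 5% to 95% inclusion, and 58.7% to 59.8% from either replicate alone, where 5850 to 6145 exons passed the read minimum because the reads were fewer. The difference in inclusion between microexons and longer exons passed its test at -8.56 points with known and new-in-catalogue transcripts only (permutation p = 0.00312) and at -5.91 points for exons of at most 51 nt (permutation p = 2.0e-05, near the smallest that 100000 permutations give). It turned positive at 0.203 points with 1 exon per gene, at 3.6 points for 10% to 90% inclusion, and at 0.197 to 1.59 points from either replicate alone, none of which passed. Apart from the inflated variance and the smaller libraries, the cause was not tested. The excess of lengths divisible by 3 among microexons passed under all 8 alternatives. The higher recovery of annotated than of unannotated chains passed at 2, 10 and 5 to 9 reads, and counts of detected genes stayed within 1.5 times under both alternatives.

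The sums of 4 lists turned to higher in replicate 2 with the length trend removed, at log2 ratios of 0.0347 (ribosomal proteins), 0.12 (nuclear oxidative phosphorylation), 0.38 (mitochondrial genome) and 0.18 (microglia), and 21 lists were called. Among single genes, lists, exons and transcripts, 453 values under an alternative stayed within the spread or the interval of the reported value, or on the same side of the test, and 94 moved by more, 49 of them with known transcripts only. Besides the 4 lists that turned, 4 lost and 1 gained a call without the trend. The log2 ratios of the 10 genes with the largest folds kept their direction and their call in all 50 cases, although most of these genes reflect assignment and not expression. No paired analysis was possible because the series has 1 group and no second group to pair. A single replicate gives no value for the difference between libraries, the BCV, detection in both libraries or the recovery of chains. Depth limits the region lists of few reads, where 3 reads equal 1.13 and 1.21 CPM.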

Other observations

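The further region markers and the strand of antisense introns were tested as fixed before those values were seen, whereas the tests of region genes without the length trend and of the strand of ERCC reads were chosen after. Outside annotated genes, the most-read antisense models shared by both libraries were single-exon models opposite Map1b, a microtubule-associated protein gene (13:99421446-99424122, 1007 and 1371 reads), Tmem170b (13:41637330-41639203, 615 and 534 reads) and Rab11fip4 (11:79694797-79697272, 470 and 649 reads). The most-read intergenic models had a single exon and lay 784 nt from Mir8091 (19:41589573-41592165, 61 and 86 reads), 595 nt from the sphingosine phosphate receptor gene S1pr3 (13:51423392-51425380, 72 and 71 reads) and 3299 nt from Fbxo42 (4:141207361-141210373, 55 and 77 reads). Of 86063 intron chains read in both libraries, 427 (0.496%) were assigned to different genes in the 2 libraries.

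Genes of neighbouring brain regions differed between the libraries: Ttr and Pmch were higher in replicate 1 and Gabra6, Doc2g and Th in replicate 2. Of the 6 genes called in the 4 region lists, 5 stayed called once the length trend was removed, which argues against that trend as the source; Enpp2 was the exception. Different amounts of neighbouring tissue in the dissections may contribute, and 2 of 4 further marker lists passed in the matching direction. Of these, the olfactory bulb list also passed without Synpr (799 and 1151 reads, adjusted p = 5.0e-21 by the exact binomial test). The choroid plexus list did not pass without Kcnj13 (45 and 30 reads, adjusted p = 0.222 by the same test). The further cerebellum list did not pass with all members. Without Car8 it had 24 and 67 reads, 3.00-fold higher in replicate 2, the matching direction (adjusted p = 2.85e-06 by the same test). The further hypothalamus list had 9 and 8 reads without Cartpt. Further olfactory bulb markers had 2350 and 2894 reads (adjusted p = 2.46e-23 by the exact binomial test, 7 of 7 tested members higher in replicate 2, among them Synpr and Meis2, and 4 without the length trend, adjusted p = 2.40e-12), and choroid plexus markers 60 and 31 (adjusted p = 0.0168, 5 of 10 read in both), whereas cerebellum markers had 217 and 214 and hypothalamus markers 14 and 16 (adjusted p = 0.589 for each), although the cerebellum sum rests on Car8 (193 and 147) and its median log2 ratio was 0.91 (percentile 99.7 among random lists, 4 members called over the list alone), against -0.81 (31.2) for choroid plexus and 0.05 (56.7) for hypothalamus, or without the length trend 0.97 (99.7), -1.01 (1.01) and 0.06 (48.55). Barhl2, Sostdc1, Agrp, Sim1 and Otp had 0 reads, and since most of these markers were read in both libraries and the reads of 3 of the 4 lists are few, tissue amounts and other sources cannot be told apart; no biological explanation was tested, as the design names none.

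Antisense models held 1.82% of reads in replicate 1 (95% Wilson interval 1.80% to 1.83%) and 1.88% in replicate 2 (1.87% to 1.90%). Of 44 ERCC sequences, 4 had all of their reads (172 and 81) on the minus strand, as a reference sequence in the other orientation would give. The remaining 40, which have no antisense transcripts, had 1 of 15114 reads on the minus strand (0.00662%, 95% Wilson interval 0.00117% to 0.0375%), so a wrong strand given at the same rate to all RNAs does not account for the antisense share. If antisense reads were sense reads given the wrong strand, their introns would be annotated on the opposite strand. That held for 28.5% of spliced antisense reads (27.9% and 29.1% by library), between the 10% and 50% set in advance against and for that explanation, so wrong strands limited to some genes may contribute and cannot be told apart from antisense transcripts by this test. The test covers spliced reads only, which were 1664 of 49227 antisense reads in replicate 1 and 1442 of 47622 in replicate 2.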
